A study of Caenorhabditis elegans with 4 samples.

How the data were processed

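The series holds 4 samples of fem-2(b245) young adults: 2 MRG-1 ChIP samples and 2 input samples, numbered 1 and 2 in each group by their labels. Per the labels' protocols, frozen adults were ground, fixed with 1% formaldehyde for 10 minutes and sonicated. Chromatin was precipitated with the affinity-purified antibody, crosslinks were reversed at 65 °C, and libraries were made from the ChIP DNA and 10 ng of input and sequenced on Illumina instruments.

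Reads were aligned with BWA to ce10, per the submitters' processing notes, with no version or setting given there. Per the file headers, the deposited peak positions are on WormBase WS220. Per the files' source column, the replicate lists came from MACS and the series-wide list from MACS v2. Versions, thresholds, duplicate handling, the use of the input, and whether replicates were pooled for the series-wide list are not given in the sources used here. Replicate lists and the series-wide list come from different caller versions, so their widths, numbers and scores are not on a common scale. Each peak carries a score deposited by the authors, whose definition the files do not give. The lowest score is 50.04 and 50.03 in the replicate lists and 1.3 in the series-wide list, and 554 peaks of replicate 1 and 272 of replicate 2 share the score 3100. Scores were used only to rank and filter peaks within a list. No file with values was used for the input samples, so no background level measured the same way can be set beside the ChIP values. A peak list says where signal passed a threshold that moves with depth, and the depth is unknown. Differences in the amount called between replicates can therefore reflect the calling as well as the chromatin.

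From these lists, coverage was computed as the percent of bases under at least 1 peak. Chromosome spans ran from base 1 to the last peak end in any list, 100 Mb in all, since no WS220 sequence was used. Centres were the middle 50% of each span and arms the outer 25% on each side. Blocks of 1 Mb, kept where at least 50% of the block was within the span, were compared by two-sided permutation tests of the mean over both replicates. Tests within 1 chromosome used exact enumeration, and other comparisons of blocks used 100000 permutations. The test of centres against arms shuffled blocks within each of the 5 autosomes. This was the planned form, but an earlier run had shuffled blocks over all autosomes together. The test was changed to the planned form after that result had been seen, and the earlier form is kept as an alternative. Overlaps of at least 1 bp were compared with 1000 circular shifts of the other list, which keep peak widths and spacing. Benjamini-Hochberg adjustment was applied over the 6 chromosomes and over the 5 autosomes. Intervals for shares of peaks are exact Clopper-Pearson intervals at 95% and cover counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

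The tests were tried on simulated lists made with replicate 2 peak widths. Simulated peaks were placed independently, without the clustering of the real lists, so the tests were not tried on clustered peaks. The mean ratios given for X and for centres are of peak numbers, not of covered bases, while the tests on those lists used block coverage. With X densities of 0.1, 0.5 and 1 times that of the autosomes, 20 lists each gave mean ratios of 0.0982, 0.496 and 0.994, and 20, 20 and 0 of them passed the threshold of 0.05. With 70% of peaks shared between lists, the excess over the shifts, as a fraction of the possible excess, averaged 0.702 over 10 runs. With none shared it averaged 0.00776, and 1 of the 10 runs passed the threshold. With centres 1.5 times as dense as arms, 20 lists gave a mean ratio of 1.51 and all 20 passed. With equal density the mean was 0.997, and 3 of the 20 passed.

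The choices above, the alternatives and the rule for named peaks were fixed before the data were examined, and alternatives added later are named as such. The rule named the 10 highest-scoring series-wide peaks and the 3 highest of each chromosome by position, with genes in their place if a WS220 annotation was at hand. It also named mrg-1 and mes-4, which lie on III and V, but their positions relative to peaks are not analysed here. The only gene table used is on WBcel235, another build, so it served for gene names and the chromosome a gene is on, and none of its coordinates were used. The 3 planned results on genes under peaks, parts of genes and 15 fixed gene lists were not run for that reason, and gene sets are described by chromosome only. The gene lists matched 40 germline genes, 36 meiotic chromosome genes, 33 sperm genes, 31 major sperm protein genes, 36 chromatin regulators, 78 cytoplasmic ribosomal protein genes, 33 proteasome genes, 33 aminoacyl-tRNA synthetase genes, 72 histone genes, 31 muscle genes, 39 neuron genes, 147 neuropeptide genes, 29 of 30 intestine genes, 163 collagen genes and 1284 chemoreceptor genes.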

Results

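The series mapped where MRG-1 sits on the chromosomes of adult Caenorhabditis elegans by chromatin immunoprecipitation and sequencing (ChIP-seq). MRG-1 is the worm member of the MRG15 family of chromodomain proteins and is known for its role in the germline. The animals carried fem-2(b245), an allele of a sex-determination gene needed for male development and sperm production, and were hermaphrodites kept at 20 °C. Their stage is labelled as young adult with a germline, while the growth protocol speaks of gravid adults, and this difference is not resolved here. ChIP was done on 2 samples with an affinity-purified rabbit polyclonal antibody raised against MRG-1. The 2 input samples, genomic DNA without immunoprecipitation, are not analysed here as separate values. The analysis rests on 3 peak lists: one per ChIP replicate and one for the whole series. Replicate 1 had 2769 peaks over 16.7 Mb and replicate 2 had 3895 peaks over 13.1 Mb, a mean of 14.9 ± 2.56 Mb (SD, n = 2). The series-wide list had 12147 peaks over 14.8 Mb. The lists carry no read counts, so the sequencing depth behind each peak is unknown. The labels do not say whether the replicates came from separate cultures, so the spread between them, and each p-value, covers these samples alone.

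MRG-1 peaks lay almost entirely on the autosomes. Peaks covered 19.7% of the autosomes and 2.61% of the X chromosome in replicate 1, and 15.8% of the autosomes and 0.323% of X in replicate 2. Autosomal coverage was thus 7.55 times that of X in replicate 1 and 49.0 times in replicate 2. The mean X to autosome ratio was 0.0764 ± 0.0792 (SD, n = 2), and the SD exceeds the mean because the replicates differ in how much of X they call. X held 191 of the peaks of replicate 1, or 6.90% (exact 95% interval 5.98 to 7.91), and 37 of replicate 2, or 0.95% (0.670 to 1.31). These intervals treat peaks as independent. X makes up 17.7% of the span analysed. In a two-sided permutation test of 1 Mb blocks, the 18 X blocks differed from the 82 autosomal blocks at p = 1e-05, the smallest value that 100000 permutations can give. Blocks are not independent replicates, so this p describes these libraries. Neighbouring blocks were also alike: by the mean of both replicates, all blocks of I from base 5000001 to 10000000 were covered to between 30.6% and 34.0%. Shuffling single blocks ignores this, so the p-values of this and the other block tests can be too small.

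**Figure D1:**
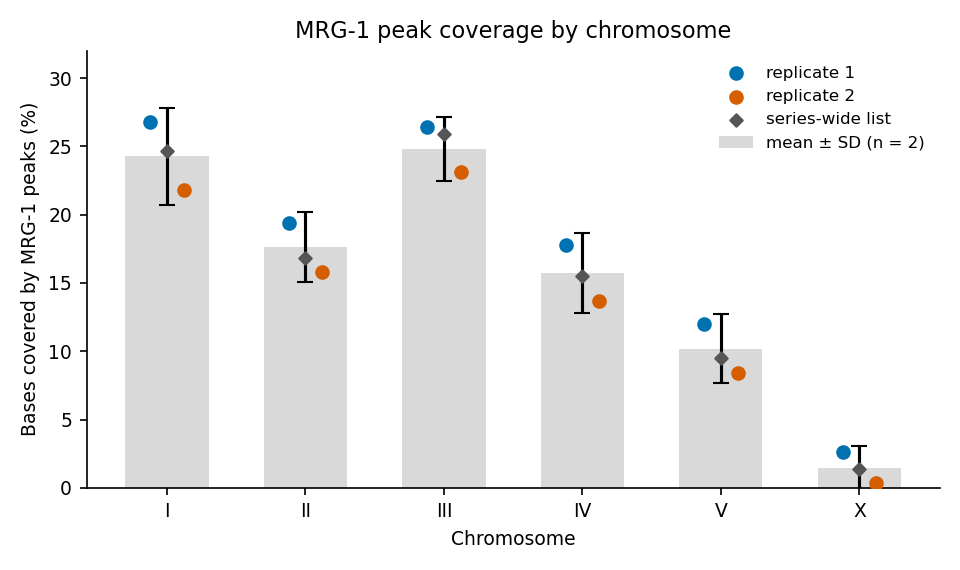
Percent of bases covered by MRG-1 peaks (vertical axis) on each chromosome (horizontal axis). Grey bars give the mean of the ChIP replicates with their SD (n = 2, drawn down to 0 on X), circles each replicate and diamonds the series-wide list, and I and III average 24.3% and 24.8% against 1.47% on X.

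The autosomes also differed among themselves. Chromosome III was covered to 24.8% ± 2.35 and chromosome I to 24.3% ± 3.56 (SD, n = 2 each). Chromosome II stood at 17.6% ± 2.55, chromosome IV at 15.7% ± 2.91 and chromosome V at 10.2% ± 2.51 (SD, n = 2 each). In both replicates V was the least covered autosome, at 11.97% and 8.42%. Against the 1 Mb blocks of the other autosomes, in two-sided tests chosen after the data were seen, those of I and III were more covered (Benjamini-Hochberg adjusted permutation p = 0.00142 and 0.00137, over 5 autosomes). The blocks of V were less covered (adjusted permutation p = 5e-05). For II and IV no difference from the other autosomes was detected (adjusted permutation p = 0.957 and 0.359), with block means of 17.7% against 17.8% and 15.8% against 18.3%. When X was among the other chromosomes, the adjusted permutation p was 6e-05 for I and for III, 0.0219 for V, 0.284 for II and 0.657 for IV, and the means of II and IV then lay above the rest (14.3% and 14.6%). By the mean of both replicates, the densest 1 Mb blocks lay in the middle of III, where bases 5000001 to 6000000 were covered to 36.1% ± 4.66 and bases 8000001 to 9000000 to 34.9% ± 0.612 (SD, n = 2 each). In replicate 1 alone these blocks stood at 32.8% and 35.3%, and the densest was on I, from 9000001 to 10000000, at 38.3%. The sparsest autosomal block was on V, from 3000001 to 4000000, at 3.32% ± 1.17 (SD, n = 2). Positions are those of WormBase WS220.

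On X the peaks were few, mostly low in score in both replicate lists, and densest at the left end. In replicate 1 only 2 of the 692 peaks in the top 25% by score lay on X, against 72 of the 693 in the lowest 25%. In replicate 2 the figures were 1 of 974 and 20 of 974. In the series-wide list X peaks were spread over the scores, with 88 of 3037 in the top 25% and 117 of 3037 in the lowest. The first 250 kb of X was covered to 18.4% in replicate 1 and 8.04% in replicate 2, while the rest of X was covered to 2.38% and 0.212%. This region was singled out after its values were seen. It was the most covered of all 71 blocks of that size on X in replicate 1, in replicate 2 and in the series-wide list. If blocks were exchangeable and the replicates independent, the block ranked first in one replicate would also lead the other with an exact probability of 0.0141. This value speaks of agreement between the replicates and would be the same for any leading block, so it does not test the left end. The series-wide list is not independent of the replicates. Of the 37 X peaks of replicate 2, 7 started there, as did 13 of the 191 of replicate 1. The highest-scoring X peak of the series-wide list was among them, at bases 45247 to 49290, and it overlapped the replicate 1 peak at 42561 to 49649 and the replicate 2 peak at 42554 to 49114.

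**Figure D2:**
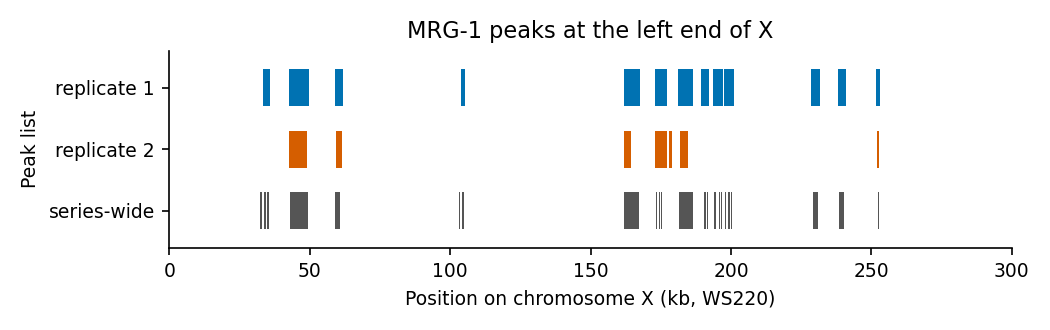
Peaks in the first 300 kb of X (horizontal axis, position in kb on WS220), drawn to scale as boxes for each of the 3 peak lists (vertical axis). Replicate 2 peaks cluster at 42554 to 61500 and at 161778 to 184863, where replicate 1 and the series-wide list also have peaks.

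Along each autosome, peaks were denser in the middle than towards the ends. C. elegans autosomes have gene-dense centres and repeat-rich arms, and the comparison asked how MRG-1 peaks divide between the middle 50% and the outer 25% on each side. The centres were covered to 23.1% in replicate 1 and 21.3% in replicate 2, and the arms to 16.3% and 10.3%. The centre to arm ratio was 1.42 in replicate 1 and 2.06 in replicate 2, with a mean of 1.74 ± 0.448 (SD, n = 2). A two-sided permutation test of 1 Mb blocks within autosomes gave p = 1e-05, again the smallest possible. In tests outside the plan, by the mean of both replicates, the centre was more covered than the arms on each autosome taken alone. The adjusted exact permutation p lay between 0.00054 for V and 0.0163 for III. A centre is 1 unbroken run of blocks, and neighbouring blocks were alike, so these p-values can be too small. The contrast was largest on V, where centres exceeded arms 1.97 times in replicate 1 and 2.48 times in replicate 2. Chromosome III was uneven between replicates: its right 25% was covered to 29.8% in replicate 1, above the 28.9% of its centre, but to 18.7% in replicate 2 against 31.8% in the centre. The centre of III held 21 strong regions of replicate 2, 468 kb in all, that had no peak in replicate 1. X had no denser centre: its middle was covered to 2.27% and 0.151%. The exact permutation test of its blocks, also outside the plan, gave p = 0.39.

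**Figure D3:**
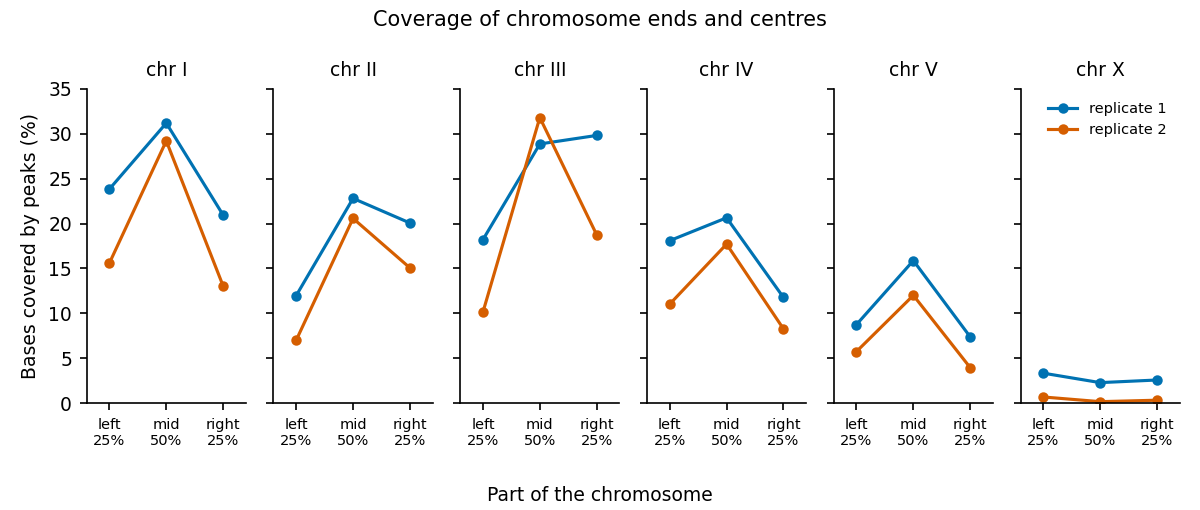
Percent of bases covered by peaks (vertical axis) in the left 25%, middle 50% and right 25% of each chromosome (horizontal axis), one line per ChIP replicate. On I, II, IV and V the middle is the highest part in both replicates, and on III it is the highest in replicate 2 but not in replicate 1.

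Stretches without peaks took up much of X and V and little of III. On X, 65 stretches of at least 100 kb had no peak in either replicate and made up 75.7% of the chromosome. On V there were 50 such stretches, or 40.4% of the chromosome, and on III there were 7, or 7.21%. The longest in the genome lay in the right 25% of IV, from 15648419 to 16360888, a length of 712 kb. The longest on V was 395 kb, from 18138091 to 18532961.

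**Figure D4:**
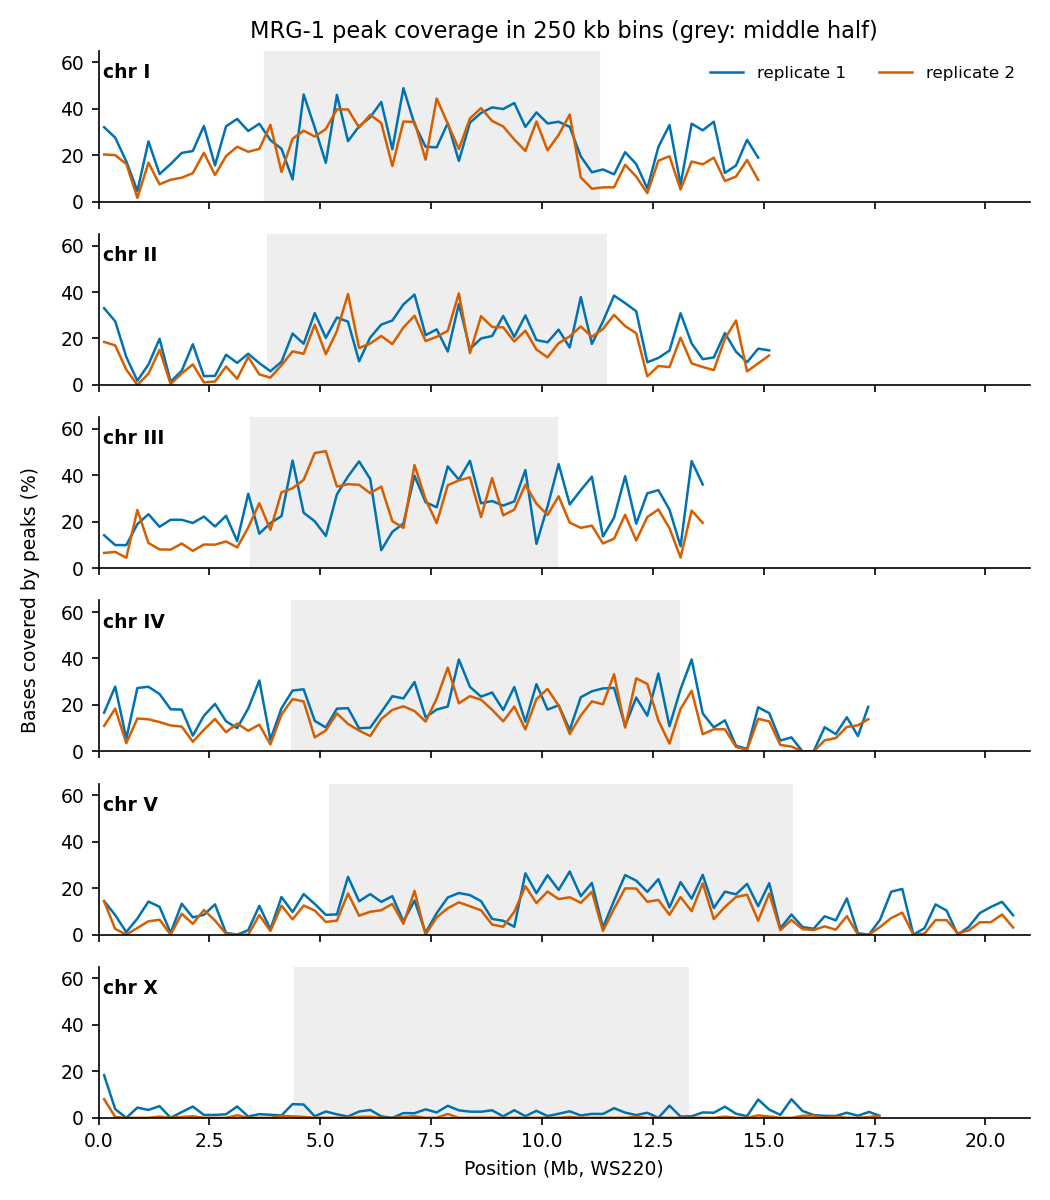
Percent of bases covered by peaks (vertical axis) in 250 kb bins along each of the 6 chromosomes (horizontal axis, position in Mb on WS220), one line per ChIP replicate, with the middle 50% shaded grey. Coverage is higher in the shaded centres of the autosomes, falls to 0 in both replicates near 16 Mb on IV, and on X exceeds 8.01% in no bin but the leftmost.

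The called peaks included broad regions as well as short sites, and their widths differed between the lists. The median peak width was 4277 bp in replicate 1 and 2163 bp in replicate 2, a mean of 3220 ± 1495 bp (SD, n = 2), and 428 bp in the series-wide list. Peaks of 10 kb or more numbered 506 in replicate 1 and 180 in replicate 2. The widest was on III in replicate 1, from 5849439 to 5882984 (33546 bp), and on I in replicate 2, from 9609023 to 9632020 (22998 bp). The median gap to the next peak was 11364 bp in replicate 1, 3638 bp in replicate 2 and 371 bp in the series-wide list.

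The peaks with the highest scores in the series-wide list were all autosomal. Of the top 10, 6 were on IV, 3 on III and 1 on II. The first was at bases 2676235 to 2678485 of IV, with a score of 67.29, and the next was at 16650242 to 16658378 of IV (67.14). The widest of these 10 was a 15284 bp peak at 13776097 to 13791380 of IV. On III the leading peaks were at 1616235 to 1623755, 1859068 to 1862039 and 5674571 to 5682207. The leading peaks were at 13652190 to 13660325 on I, 12459233 to 12461357 on II and 20493381 to 20495331 on V. All 18 of the autosomal peaks in the top 10 or the top 3 of a chromosome overlapped a peak in both replicates. Their standing by score in the replicate lists varied. The first lay at percentiles 71.6 and 63.9 of replicates 1 and 2, and the second at 99.3 and 84.4. The 15284 bp peak lay at 53.3 and 75.5. In the series-wide list the leading X peak ranked 233. The next ranked 1027, at 7474157 to 7475333, and had no peak in replicate 2. The scores are the authors' own and order peaks within that list only. Whether these positions fall in genes is not given, because the gene table used here is on another genome build.

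The replicates shared most of their strong peaks. In replicate 1, 72.9% of the peaks overlapped a replicate 2 peak by at least 1 bp, and in replicate 2, 82.6% overlapped a replicate 1 peak. Circular permutation, which shifts the other list along each chromosome, gave means of 30.8% and 29.4% and highest values of 36.9% and 38.05% (two-sided permutation p = 0.001 for each, the smallest that 1000 shifts can give). Among the top 25% of replicate 1 peaks by score, 99.0% were overlapped in replicate 2, against 31.9% of the lowest 25%. In replicate 2 the figures were 88.7% and 70.6%. The top 25% were also wider, with medians of 8072.5 against 1772 bp in replicate 1 and 5972 against 1013 bp in replicate 2. Wider peaks meet a 1 bp overlap more easily. The shifts were not run within these score groups, so score and width are not separated. On X, 15.7% of the replicate 1 peaks were overlapped (exact 95% interval 10.9 to 21.7), against 75.3% to 80.1% on the autosomes, whereas 33 of the 37 replicate 2 peaks on X were. With only 37 replicate 2 peaks on X, few of the 191 replicate 1 peaks there could be overlapped. The 15.7% is therefore bounded by the calls and does not show that X peaks were less reproducible. Bases covered in both replicates came to 10.8 Mb, or 56.7% of those covered in either, and 51.6 kb of them lay on X. Some strong regions of replicate 2 had no peak at all in replicate 1. Joining replicate 2 peaks over gaps of up to 1 kb gave 896 runs with a peak in the top 25% by score, and 81 of these, 1334 kb in all, had no replicate 1 peak. Chromosome I had 27 of them, III 25, II 15, IV 11 and V 3. They included all 10 runs over 30 kb, 8 of them on III, led by bases 6414666 to 6471743 of III. The series-wide list had peaks in all 81.

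The series-wide list overlapped nearly all replicate peaks, in finer pieces. By at least 1 bp, it overlapped 99.7% of the replicate 1 peaks and 95.7% of those of replicate 2. The mean was 3.39 and 1.83 series-wide peaks per replicate peak. Of its own peaks, 44.5% overlapped both replicates, 32.8% replicate 1 alone, 9.08% replicate 2 alone and 13.6% neither. Among the top 25% by score, 77.1% overlapped both and 1.81% neither, while 25.7% and 25.6% of the lowest 25% did. The top 25% were also wider (median 2586 bp against 229 bp), which makes an overlap easier to reach. Peaks found in neither had a median width of 227 bp, against 861 bp for those in both. On X, where replicate 2 had only 37 peaks, 9.91% of the series-wide peaks overlapped both replicates and 74.1% replicate 1 alone. Coverage in this list was 17.6% on the autosomes and 1.36% on X, a ratio of 0.0770, and 1.79 times as high in autosome centres as in arms. The list is not independent of the replicates, so these shares describe it and test nothing.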

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

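The alternatives with the replicate 2 runs left out, per gene, for bases in both replicates, without chromosome III, without the first 1 Mb of X and with blocks shuffled over all autosomes were added after the data were seen, as were those for the pairing centre arms and the left end of X. Coverage of X stayed below that of the autosomes and past the threshold under all 11 alternatives, with ratios from 0.0184 for the top 50% of each list by score to 0.195 for peaks per Mb. The ratio rests on which replicate is used: 0.0204 without replicate 1 and 0.132 without replicate 2. The centre to arm ratio stayed above 1 and past the threshold under all 9 alternatives, from 1.42 without replicate 2 to 2.06 without replicate 1. Not all of these alternatives could move the ratios. Other block sizes, and the shuffle over all autosomes, change only the test. The series-wide list is not independent of the replicates, so the alternatives are not separate pieces of support. Replicate overlap stayed above the shifted lists under all 3 alternatives for each replicate. With at least 50% of the peak covered, 58.2% of replicate 1 and 81.6% of replicate 2 peaks were shared. With the top 50% of both lists, 87.6% and 71.9% were. Of series-wide peaks, 40.9% lay in both replicates and 14.3% in neither when at least 50% of the peak had to be covered, and 60.7% and 4.97% for the top 50% by score. The cause of the latter shift was not tested. In the top 50% of the replicate lists the median width was 5667 bp and the median gap 24452 bp, as fewer peaks lengthen the gaps and width rose with score: from the lowest to the top 25%, median widths were 1772 and 8072.5 bp in replicate 1 and 1013 and 5972 bp in replicate 2. No paired analysis was possible because the input samples have no values here to pair with the ChIP samples of the same number. Genes under peaks, gene parts and gene lists, with their alternatives, were not run, since no annotation on the build of the peaks was used. Depth is unknown, so whether more X sites would be called with more reads cannot be read from these lists.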

Other observations

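The tests in this part on the top 25% of replicate 1, unrelated X signal, joined peaks and the pairing centre arm were set before their results were seen. Those on the top 50% of each list, gene number, the autosome arms and the missing domains, and the Fisher tests of gene lists, were chosen afterwards.

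The gene groups fixed for this study sit on chromosomes that differ widely in MRG-1 coverage, by the chromosome each gene has in the WBcel235 gene table. None of the 40 germline genes, among them pgl-1, glh-1, glp-1 and gld-1, and none of the 36 meiotic chromosome genes, such as him-3, htp-3, syp-1 and rec-8, is on X. The sperm list (0 of 33), the major sperm protein genes (0 of 31), the proteasome genes (0 of 33) and the aminoacyl-tRNA synthetase genes (0 of 33) are also absent from X, and 2 of 78 cytoplasmic ribosomal protein genes are there. All of these lists had fewer X genes than other protein-coding genes (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p from 0.0074 to 0.0273 over 15 lists). Neuropeptide genes, with 37 of 147 on X (Fisher's exact test, adjusted p = 0.00121), and intestine genes, with 9 of 29, among them vit-2, vit-5 and elt-2 (adjusted p = 0.0273), had more. Muscle (8 of 31, including myo-2 and unc-27), neuron (7 of 39), collagen (27 of 163), histone (4 of 72) and chromatin regulator genes (5 of 36, including utx-1) did not pass the test. Chromosome V, the least covered autosome, carries 872 of the 1284 chemoreceptor genes, which are known for expression in sensory neurons. Only 31 of these are on X (Fisher's exact test, adjusted p = 8.62e-46). Genes of a family in tandem are not independent, and these counts do not show which genes lie under peaks.

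The low coverage of X was not matched by its gene number. X carries 2730 of 19971 protein-coding genes. If the number of protein-coding genes per chromosome set the coverage, covered bases per gene on X would be close to those on the autosomes. They were 169 bp against 942 bp in replicate 1 and 20.9 bp against 755 bp in replicate 2, ratios of 0.180 and 0.0277. Gene number therefore does not account for the low X coverage, and the activity of those genes in the germline stays open as an untested biological explanation.

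A hypothesis tested here was that MRG-1 is denser on the autosome arm with the meiotic pairing centre, the end at which homologues first pair (the right end of I, IV and V and the left end of II and III). The data went the other way: the outer 25% on the pairing centre side was less covered than the opposite 25% on 5 of 5 autosomes in both replicates. The difference, pairing centre side minus opposite side, averaged -5.41 ± 3.60 percentage points (SD over the 5 autosomes, mean of both replicates). A two-sided exact sign-flip test gave p = 0.0625, the smallest that 5 autosomes allow, so the threshold of 0.05 cannot be reached. With the outer 10% on each side the mean difference was -4.21, in that direction on 4 of 5 autosomes, with I the exception (exact p = 0.312). Taken singly, replicate 1 had that direction on 3 of 5 (exact p = 0.438) and replicate 2 on 4 of 5 (exact p = 0.188). With 1 in 3 of the length on each side it was -4.25, in that direction on 5 of 5. X was the reverse, since its pairing centre end is the left end with the peak cluster. Gene density of the arms was not compared.

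Replicate 1 called a larger share of its peaks on X than replicate 2, 6.90% against 0.95%. Weak peaks, added by a more permissive call or greater depth, are 1 possible explanation, but the planned test does not decide: the X share in the top 25% of replicate 1 by score was 0.289% (exact 95% interval 0.0350 to 1.04), and that of replicate 2 fell in the same way, to 0.103% in its own top 25%. Between the top 50% of each list the excess remained, at 1.23% (0.717 to 1.96) against 0.257% (0.0834 to 0.598; two-sided Fisher's exact p = 0.000818), although 1.23% is not above the interval of the whole replicate 2 list (0.670 to 1.31), and how strictly each list was called is unknown. Unrelated signal in replicate 1 also stays open: 33 of the 37 replicate 2 peaks on X were overlapped by replicate 1, with a mean of 1.56 and at most 7 in 1000 circular shifts, but the planned bound on that count says nothing of the 161 of 191 replicate 1 peaks on X without a counterpart. Most of those 161 could have none, since replicate 2 had only 37 peaks on X. Both samples belong to one group, so no biological explanation was tested.

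Replicate 1 also covered the autosome arms more, 1.57 times as much as replicate 2, against 1.09 times in the centres. Leaving out low-scoring peaks did not remove this: the centre to arm ratio of replicate 2 was 1.60 times that of replicate 1 between the top 50% of each list (block bootstrap 95% interval 1.41 to 1.84), and 1.34 times (1.19 to 1.51) between all of replicate 2 and the top 50% of replicate 1. Both values keep the missing runs described next, and how strictly each list was called is unknown. A share of weak peaks in the difference therefore stays open. A candidate explanation is that some wide domains are missing from the replicate 1 list: 100% of the 10 strong replicate 2 runs over 30 kb lacked a replicate 1 peak, against 34.3% of 35 runs of 20 to 30 kb and 6.93% of 851 shorter ones (two-sided Fisher's exact p = 5.81e-12, longest against shorter). Leaving out all 81 missing runs, 67 of them in autosome centres, lowered the quotient from 1.43 to 1.31 (interval 1.24 to 1.39), so these runs are not the whole difference. The runs were picked for lacking a replicate 1 peak and lay mostly in centres, so a fall was built in. Regions that replicate 1 called only in part were kept. The remaining 1.31 therefore does not show how much of the difference missing calls make up. Replicate 1 did hold 3 strong runs over 30 kb and 28 of 20 to 30 kb, and the bound of under 5% set for the shorter missing runs was not met, so whether width, or a filter that the sources used here do not give, set what is missing stays open.

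Replicate 1 peaks were wider than replicate 2 peaks, 1.98 times by the median. Among 1167 autosomal peaks that matched 1 to 1 between the lists, the ratio was 1.37 (bootstrap 95% interval 1.34 to 1.42). Joining of neighbouring peaks could account for part of the width, and 775 replicate 1 peaks did span more than 1 replicate 2 peak. The ratio lies between the bounds set beforehand, 1.1 or less if joining were the cause and 1.5 or more if not. A matched replicate 1 peak can include a neighbour that was not called in replicate 2, so the test leaves joining open.

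The longest stretch without a peak in either replicate, 712 kb on the right arm of IV, lies on the chromosome that carries 14714 of the 15363 piRNA genes in the gene table. Their positions relative to this stretch were not compared.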
